A study of Caenorhabditis elegans with 15 samples.

How the data were processed

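Total RNA was taken from pools of N2 hermaphrodites at L4, L4-lethargus and Adult, with 5 arrays per stage and 20 animals per batch, per the labels' protocols. Animals were cultured at 20 °C and collected at 22.5 °C. Samples with an RNA integrity number above 5 were used and 1 sample per stage was left out by the authors, per the labels. RNA was amplified with the NuGEN Ovation V2 kit and hybridised to the Affymetrix C. elegans Genome Array. The deposited values are log2 expression values made by the authors with RMA (robust multi-array average: background correction, quantile normalization and a summary per probe set), per the submitters' processing notes, which state no version. The probe annotation build is not given in the sources used here. RMA makes the arrays' distributions similar, so an overall rise or fall of RNA in a stage cannot be read from these values. The array medians still differed by stage, at 7.47 ± 0.05 in L4, 7.51 ± 0.02 in lethargus and 7.26 ± 0.04 in Adult (log2, SD over 5 arrays each), an offset that median-centring removes. RMA also leaves a floor of background signal, so folds of dim genes are understated.

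The table held 22625 probe sets, of which 77 were Affymetrix controls and were left out of the tests. Of the 22548 tested, 20766 named 1 gene, 887 named several and 895 were not named in the annotation used. Of the probe sets with 1 gene, 20701 were matched by gene id to the reference table, and 0 symbols changed. No gene was named from a probe set with several. A gene with more than 1 probe set (2981 genes) was read from the probe set with the highest mean, giving 17118 genes. Probe sets with the suffix _s_at (5484) or _x_at (1227) share probes with other transcripts, so genes of the *abu*, *vit* and histone families read from them cannot be told apart from their close relatives.

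Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 15 arrays, with a mean for each of the 3 stages and 1 shared spread. As in the series design, p-values were multiplied by 2. They were then adjusted by the Benjamini-Hochberg method over 22548 probe sets, and an adjusted p of 0.05 or less was called, with no fold minimum. The series design names R/maanova with permutation p-values, which was not run here, and permutation p-values of the limma statistic were tried as an alternative. Every adjusted p of a gene is from limma. Errors after ± are SDs over the 5 arrays of a stage. The labels describe pools of animals, and nothing states how far the pools of a stage were grown separately, so p-values measure the spread between these pools.

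Where the dimmer stage had a mean below 5.56 log2, the 95th percentile of 32 control probe sets of other organisms, its level is a bound and the change is written as at least N-fold, with the dim mean set to that bound. No fold is given where both stages lie below it. This bound was chosen after seeing the data.

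Gene lists (34), the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 largest rises and 6 largest falls among named genes that passed and whose arrays did not overlap, and at most 3 members of each list with the largest difference among those that passed, or 1 where none passed. It also took *nlp-22*, *flp-11*, *flp-13*, *aptf-1* and *lin-42* in every comparison, the 8 highest and 8 lowest genes for lethargus against both stages, and at most 2 members of an enriched gene class. Lists were tested with camera, which sets a list against all other genes, so that its direction can differ from the sign of the median, at an inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 34 lists. Classes of gene names with at least 10 members (165 classes, 10388 genes) were tested with Fisher's exact test.

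The procedure was tested on simulated data for the comparison of lethargus with L4, with 22548 probe sets of which 200 were changed. It recovered 66% of changes of 1.5-fold, 92% of 2-fold and 100% of 4-fold and 8-fold, with 6 false calls. Alternatives were another scaling (median-centring of each array, quantile normalization again, cyclic loess), a filter on dim probe sets (mean below the 40th percentile), p-values not doubled, permutation p-values, 2 groups only in the fit, a log2 difference of at least 1, a trended robust prior, array quality weights, a replicate block, leaving out each array in turn, leaving out shared-probe probe sets, other rules for genes with several probe sets, and estimated correlation for lists. Scaling to the hybridisation control probe sets and leaving out 3 arrays together were added after seeing the data. Figures were drawn with matplotlib 3.10.9.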

Results

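RNA from pools of wild-type N2 Caenorhabditis elegans hermaphrodites was measured on Affymetrix C. elegans Genome Arrays at 3 stages. These were the last larval stage (L4), the lethargus that closes it (L4-lethargus) and Adult. Lethargus is a period of quiescence at each larval molt, in which feeding and locomotion stop and the new cuticle is completed. Each stage had 5 arrays, 15 in all, and the labels describe pools of 20 animals per batch. L4 animals were taken 42 h after feeding, and lethargus animals 45 to 50 h after feeding and 30 to 40 min after pharyngeal pumping had stopped. RNA yields stated in the labels were 22.3 ± 7 ng for L4, 18.6 ± 3.5 ng for lethargus and 75.3 ± 10.3 ng for Adult. Values are the deposited log2 intensities of 22548 probe sets other than controls, which represent 17118 named genes read from 1 probe set each. The number of arrays per stage limits the precision of every comparison. Run order is not stated, so it cannot be told apart from stage. The 3' minus 5' differences of the control transcripts, a sign of RNA quality, gave no single order of the stages. For L4, lethargus and Adult they were 4.63 ± 0.10, 4.38 ± 0.12 and 4.28 ± 0.19 for ubiquitin, 3.22 ± 0.32, 3.05 ± 0.17 and 2.67 ± 0.26 for catalase, 0.12 ± 0.12, 0.06 ± 0.07 and 0.29 ± 0.12 for GAPDH and 0.05 ± 0.08, 0.04 ± 0.04 and 0.12 ± 0.09 for actin (log2, SD, n = 5 each).

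Arrays of 1 stage correlated at r = 0.983 to 0.997 across probe sets, and the first 2 principal components carried 61.9% and 27.3% of the variance. The lethargus arrays lay between L4 and Adult on the first component and apart from both on the second. Lethargus replicate 1 lay nearest to L4 among the lethargus arrays, with a score of -40.8 on the first component against -14.6 to 4.15 for the others. Adult replicate 2 had the lowest mean correlation with its own stage (0.987, against 0.994 to 0.995 for the other Adult arrays). Identical values never filled more than 180 of the 22548 probe sets in any pair of arrays of a stage.

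**Figure D1:**
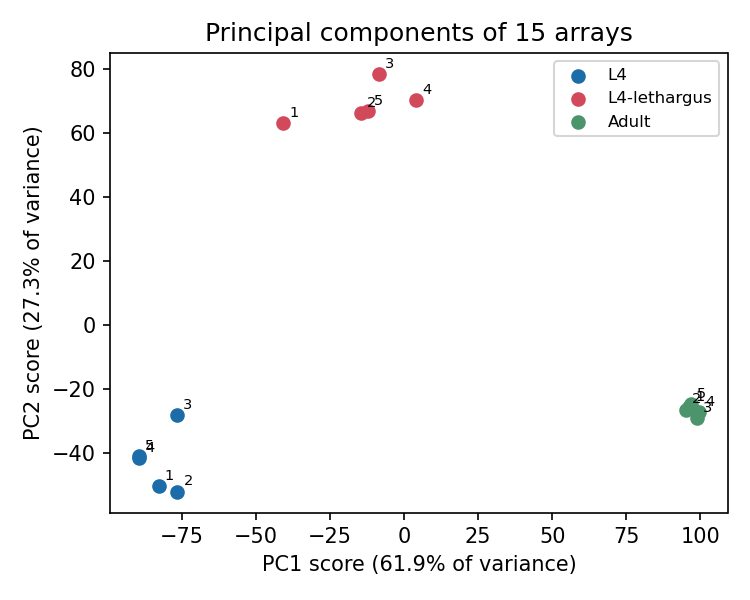
Scores of the 15 arrays on the first 2 principal components of the log2 values, with 61.9% of the variance on the horizontal axis and 27.3% on the vertical axis. Each point is 1 array, coloured by stage and numbered by replicate, and the 5 lethargus arrays stand apart from the L4 and Adult arrays on the vertical axis.

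The comparison of lethargus with L4 asks which transcripts differ but cannot tell quiescence from molt, age or stopped feeding. Genes of the pharyngeal and body cuticle were among the largest rises and genes of the precuticle matrix among the largest falls. The pharyngeal cuticle genes *abu-15*, *abu-6* and *abu-8* were at least 138-fold, at least 124-fold and at least 137-fold higher in lethargus, and the adult-stage collagen gene *col-19* rose by 6.09 on the log2 scale. The lipocalin genes *lpr-3* and *lpr-5*, which act in the transient precuticle, were 86.7-fold and at least 58.1-fold lower, *lpr-4* differed by -6.48 in log2, and yolk protein and oocyte genes rose.

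In all, 3511 probe sets (2733 genes) rose and 3455 (2673 genes) fell at an adjusted p of 0.05 or less by limma, out of 22548. The log2 value of *abu-15* was 12.67 ± 0.37 in lethargus and 4.15 ± 0.27 in L4 (SD, n = 5 arrays each, adjusted p = 2.83e-15), and its probe set shares probes with other *abu* genes. *dct-5* had 11.59 ± 0.11 in lethargus and 3.51 ± 0.12 in L4 (SD, n = 5 each, adjusted p = 2.91e-17). *dbd-20* rose by 6.66 on the log2 scale and the ground-like gene *grl-4* 87.5-fold (adjusted p = 3.36e-12 and adjusted p = 4.12e-16). Among the falls, *lpr-5* had 11.42 ± 0.42 in L4 and 4.83 ± 0.72 in lethargus (SD, n = 5 each, adjusted p = 3.19e-11). The mucin-like gene *osm-8* fell at least 55.4-fold, the warthog gene *wrt-1* 75.6-fold and *spia-1* 70.8-fold (adjusted p = 9.92e-13, adjusted p = 2.25e-10 and adjusted p = 2.06e-09). For each of these genes no L4 array overlapped the lethargus arrays.

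Cuticle genes moved in both directions. Of the cuticle collagens, 73 of 146 rose, 33 fell and 40 were not called (77 and 37 adjusted over the list alone). Their median was 0.33 in log2 (camera adjusted p = 5.21e-05, adjusted p = 0.278 with an estimated correlation). *col-129* and *col-39* rose 86.4-fold and 68.1-fold. Of the furrow collagens, which shape the annular furrows, 0 of 5 rose, 5 fell and 0 were not called (0 and 5 adjusted over the list alone). Their median was -4.97 in log2 (camera adjusted p = 3.48e-08, adjusted p = 0.124 with an estimated correlation). Among them *dpy-8*, *dpy-7* and *dpy-9* fell 56.5-fold, 40.6-fold and 31.4-fold. Of the collagens known from the adult cuticle, 1 of 8 rose, 6 fell and 1 was not called (1 and 7 adjusted over the list alone). Their median was -2.19 in log2 (camera adjusted p = 0.0253, adjusted p = 0.398 with an estimated correlation). In that list *col-19* rose, while *bli-1* and *bli-2*, which form struts of the adult cuticle, fell 38.9-fold and 20.4-fold. That call ended without dim probe sets (adjusted p = 0.0522) and without shared-probe probe sets (0.220).

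Most molting genes were lower in lethargus, while related lists moved in both directions. Of the molting regulators and enzymes, 5 of 36 rose, 25 fell and 6 were not called (6 and 26 adjusted over the list alone). Their median was -1.26 in log2 (camera adjusted p = 8.21e-08, adjusted p = 0.233 with an estimated correlation), led by *noah-2* (44.4-fold lower), the hedgehog-related *qua-1* (at least 24.8-fold lower) and *ptr-4* (19.7-fold lower). Of the apical matrix and zona pellucida proteins, 8 of 50 rose, 19 fell and 23 were not called (9 and 20 adjusted over the list alone). Their median was -0.11 in log2 (camera adjusted p = 0.00372, adjusted p = 0.239 with an estimated correlation), and -0.05 after scaling to the hybridisation controls, -0.06 without L4 replicate 1, -0.25 without shared-probe probe sets and -2.22 without dim probe sets. Of the hedgehog-related proteins, 17 of 54 rose, 21 fell and 16 were not called (17 and 21 adjusted over the list alone). Their median was -0.11 in log2 (camera adjusted p = 0.309), with *grl-4* up and *wrt-1* and *wrt-2* down (56.8-fold for the last). Of the patched-related proteins, 7 of 26 rose, 12 fell and 7 were not called (7 and 12 adjusted over the list alone). Their median was -0.20 in log2 (camera adjusted p = 0.309). Of the astacin metalloproteases, secreted enzymes of which several act in molting, 21 of 36 rose, 5 fell and 10 were not called (21 and 5 adjusted over the list alone). Their median was 0.89 in log2 (camera adjusted p = 3.01e-05, adjusted p = 0.0464 with an estimated correlation). *nas-30* and *nas-5* rose 15.9-fold and at least 12.5-fold, and *toh-1* had 9.96 ± 0.34 in lethargus and 4.82 ± 0.23 in L4 (SD, n = 5 each, adjusted p = 1.13e-12), and its other probe sets passed at 6.08 and 9.93 in lethargus, with L4 not above background. Without dim probe sets the astacin median was 1.54, and without shared-probe probe sets the molting median was -0.76. Some lists share members, such as *noah-2* and *qua-1*, so their tests are not independent.

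Most measured pharyngeal, oogenesis and yolk genes rose in lethargus. Of the pharyngeal muscle and gland genes, 18 of 26 rose, 2 fell and 6 were not called (18 and 2 adjusted over the list alone). Their median was 1.13 in log2 (camera adjusted p = 1.92e-08, adjusted p = 0.233 with an estimated correlation), and 9 of the 11 *abu* genes, which the list includes, rose. The 2 members that fell were *abu-12* (3.42-fold) and *abu-13* (9.99-fold), both read from shared-probe probe sets and named here after their values were seen, and the *abu-12* call ended with the 2 groups alone in the fit (adjusted p = 0.0552). Of the oogenesis and eggshell genes, 28 of 33 rose, 0 fell and 5 were not called (29 and 0 adjusted over the list alone). Their median was 1.49 in log2 (camera adjusted p = 6.01e-16, adjusted p = 0.233 with an estimated correlation). The vitelline layer genes *perm-2* and *perm-4* rose 11.9-fold and 7.24-fold, and the chondroitin proteoglycan gene *cpg-3* 9.52-fold. All 5 measured vitellogenins, the yolk protein genes of the adult intestine, rose, with a median log2 difference of 3.34 (camera adjusted p = 3.34e-07, adjusted p = 0.0464 with an estimated correlation, 5 and 0 adjusted over the list alone). *vit-2* went from 9.91 ± 0.27 to 13.24 ± 0.04 (SD, n = 5 each, adjusted p = 9.92e-13), and *vit-5* and *vit-4* were 39.6-fold and 35.5-fold higher, read from probe sets with shared probes, and the other probe sets of *vit-4* differed by 5.24 and 3.43 in log2. The vitellogenins and the astacins were the lists whose call held with an estimated correlation, and no list call against Adult or between Adult and L4 held with it. Of the chitinases and chitin-binding genes, 8 of 36 rose, 4 fell and 24 were not called (8 and 4 adjusted over the list alone). Their median was 0.08 in log2 (camera adjusted p = 0.0563). They passed without L4 replicates 3 or 4 or lethargus replicate 2, taken singly (adjusted p = 0.0491, 0.0476 and 0.0343), and with a trended robust prior (0.0431).

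Most of the known lethargus genes were not called. Of the sleep and lethargus regulators, 8 of 36 rose, 3 fell and 25 were not called (8 and 3 adjusted over the list alone). Their median was 0.12 in log2 (camera adjusted p = 0.531). The neuropeptide genes *flp-11* and *flp-13*, which promote quiescence, differed by 0.35 and 0.43 log2 units and did not pass (adjusted p = 0.163 and adjusted p = 0.0585). *nlp-22*, another such gene, was at 5.80 ± 0.16 in L4 and, not above background, at 5.51 ± 0.12 in lethargus (SD, n = 5 each), and did not pass (adjusted p = 0.195). *flp-13* passed with cyclic loess (adjusted p = 0.0483), with p-values not doubled (0.0292), without L4 replicate 1 (0.0274) and without Adult replicate 2 (0.0413), and *flp-11* without L4 replicate 5 (0.0282). *aptf-1*, a transcription factor needed in the sleep-promoting RIS neuron, was not above background at any stage, so no difference is read for it in any comparison. *lin-42*, the period homologue that cycles with the molts, fell from 10.45 ± 0.13 to 8.97 ± 0.29 (SD, n = 5 each, adjusted p = 8.75e-08), and a second probe set for it fell by 0.38 on the log2 scale. Within the same list the epidermal growth factor gene *lin-3* rose 1.93-fold and the receptor gene *frpr-4* fell at least 1.34-fold. Of the heterochronic genes, 3 of 14 rose, 5 fell and 6 were not called (3 and 5 adjusted over the list alone). Their median was -0.10 in log2 (camera adjusted p = 0.426), including *lin-46* (at least 2.94-fold higher), *mab-10* (at least 2.47-fold lower) and *lin-41* (3.10-fold higher). The second probe sets of *lin-41* and *lin-46* were not above background in either stage. The heterochronic median turned above 0 with the probe set of largest spread or the mean of the probe sets (0.01 and 0.0048).

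The neuropeptide lists had medians slightly above 0 in lethargus against L4. Of the FMRFamide-like neuropeptides, 6 of 25 rose, 0 fell and 19 were not called (5 and 0 adjusted over the list alone). Their median was 0.25 in log2 (camera adjusted p = 0.0138, adjusted p = 0.331 with an estimated correlation). *flp-3* and *flp-21* rose 1.47-fold and 1.34-fold. *flp-17* rose 1.56-fold (adjusted p = 0.0487), but the call ended when any 1 of 13 arrays was left out, all but L4 replicates 3 and 5, with adjusted p of 0.0527 to 0.133, and also with median-centring, quantile normalization again, array weights, the 2 groups alone, permutation p-values, scaling to the hybridisation controls or the 3 arrays left out together (0.0512 to 0.112). Of the other neuropeptide-like proteins, 10 of 52 rose, 1 fell and 41 were not called (9 and 1 adjusted over the list alone). Their median was 0.21 in log2 (camera adjusted p = 0.0114, adjusted p = 0.398 with an estimated correlation), and *nlp-67* rose at least 14.4-fold and *nlp-62* 4.98-fold. Of the synaptic vesicle and transmitter genes, 4 of 37 rose, 2 fell and 31 were not called (4 and 2 adjusted over the list alone). Their median was 0.00 in log2 (camera adjusted p = 0.633), a median that turned below 0 under 5 alternatives, furthest to -0.04 after median-centring of each array. There *tbh-1* and *tdc-1*, octopamine and tyramine synthesis enzymes also made in gonadal sheath cells, rose at least 6.78-fold and 2.00-fold. Of the other probe sets of *tdc-1*, 1 passed at 6.12 in lethargus, with L4 not above background, and 1 did not pass (-0.06 in log2). Of the insulin-like peptides, 4 of 24 rose, 1 fell and 19 were not called (1 and 1 adjusted over the list alone). Their median was 0.19 in log2 (camera adjusted p = 0.292), and *ins-35* fell at least 4.48-fold. Of the epidermal antimicrobial peptides, 9 of 18 rose, 1 fell and 8 were not called (9 and 1 adjusted over the list alone). Their median was 0.51 in log2 (camera adjusted p = 0.00574, adjusted p = 0.259 with an estimated correlation), with *cnc-4* up 9.34-fold and *cnc-3* down 30.8-fold, and that median was 0.92 without dim probe sets.

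Heat shock, muscle and housekeeping lists had medians slightly below 0. Of the heat shock proteins, 1 of 21 rose, 8 fell and 12 were not called (1 and 8 adjusted over the list alone). Their median was -0.26 in log2 (camera adjusted p = 0.00511, adjusted p = 0.233 with an estimated correlation), with the small heat shock genes *hsp-16.41* and *hsp-16.2* down 23.3-fold and 11.8-fold and *hsp-43* up 2.35-fold. Of the unfolded protein response genes, 0 of 23 rose, 7 fell and 16 were not called (0 and 5 adjusted over the list alone). Their median was -0.21 in log2 (camera adjusted p = 0.00436, adjusted p = 0.259 with an estimated correlation), including the disulfide isomerase gene *pdi-2* and the BiP gene *hsp-4* (1.46-fold and 1.45-fold lower). That call ended without shared-probe probe sets (adjusted p = 0.0592). Of the cytosolic ribosomal proteins, 0 of 74 rose, 3 fell and 71 were not called (0 and 1 adjusted over the list alone). Their median was -0.12 in log2 (camera adjusted p = 1.51e-04, adjusted p = 0.371 with an estimated correlation). Of the oxidative phosphorylation genes, 0 of 40 rose, 10 fell and 30 were not called (0 and 8 adjusted over the list alone). Their median was -0.16 in log2 (camera adjusted p = 3.70e-04, adjusted p = 0.149 with an estimated correlation). Of the body wall muscle structural genes, 0 of 27 rose, 7 fell and 20 were not called (0 and 5 adjusted over the list alone). Their median was -0.15 in log2 (camera adjusted p = 0.00574, adjusted p = 0.239 with an estimated correlation). Cyclic loess ended the ribosomal and muscle calls (adjusted p = 0.276 and 0.0605). Cyclic loess and scaling to the hybridisation controls brought the medians nearer 0, at -0.02 and -0.05 for the ribosomal, -0.09 and -0.09 for the oxidative phosphorylation and -0.08 and -0.08 for the muscle list, whose median was -0.35 without shared-probe probe sets. *ttn-1* and *unc-22*, giant muscle proteins, fell 1.44-fold and 1.44-fold, and neither passed when the mean of its probe sets was used (adjusted p = 0.160 and 0.105). With the probe set of largest spread *unc-22* did not pass (adjusted p = 1), nor did *ttn-1* by permutation (0.059), and none of the other probe sets of *ttn-1* passed (-0.34 to -0.07 in log2, 1 of them not above background). Without any 1 of 5 arrays *ttn-1* had an adjusted p of 0.0632 to 0.093.

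Of the fasting response genes, 6 of 21 rose, 4 fell and 11 were not called (7 and 4 adjusted over the list alone). Their median was 0.09 in log2 (camera adjusted p = 0.426), and *acs-2*, an acyl-CoA synthetase gene induced by starvation, rose 4.62-fold (adjusted p = 4.11e-05) while the lipase gene *lipl-2* rose 3.02-fold. Of the fatty acid desaturases and elongases, 1 of 15 rose, 6 fell and 8 were not called (1 and 6 adjusted over the list alone). Their median was -0.17 in log2 (camera adjusted p = 0.0389, adjusted p = 0.398 with an estimated correlation), with the elongase genes *elo-4* and *elo-7* down 6.42-fold and 2.04-fold. That call ended without L4 replicates 1 or 5 or lethargus replicate 4, taken singly, at adjusted p of 0.0516 to 0.0848, and with median-centring, quantile normalization again, cyclic loess, scaling to the hybridisation controls or no shared-probe probe sets (0.0518 to 0.129), the median being -0.11 after scaling to the hybridisation controls. Of the intestinal digestive proteases, 1 of 17 rose, 6 fell and 10 were not called (1 and 6 adjusted over the list alone). Their median was -0.17 in log2 (camera adjusted p = 0.0452, adjusted p = 0.398 with an estimated correlation). That call ended without L4 replicates 1, 4 or 5 or lethargus replicates 2 or 4, taken singly, at adjusted p of 0.0523 to 0.0712, and with quantile normalization again, cyclic loess, scaling to the hybridisation controls, no dim or no shared-probe probe sets or the probe set of largest spread (0.0515 to 0.216), the median being -0.09 and -0.10 with cyclic loess and scaling to the hybridisation controls and -0.11 without shared-probe probe sets. Of the lysozymes and saposin-like proteins, 5 of 34 rose, 10 fell and 19 were not called (5 and 10 adjusted over the list alone). Their median was -0.06 in log2 (camera adjusted p = 0.315). Of the C-type lectins, 20 of 220 rose, 29 fell and 171 were not called (15 and 27 adjusted over the list alone). Their median was -0.03 in log2 (camera adjusted p = 0.387). Both medians turned above 0 after scaling to the hybridisation controls (0.0058 and 0.04), the lectin median also with array weights and without L4 replicate 2 (0.02 and 0.01). Of the coelomocyte and glia markers, 1 of 11 rose, 6 fell and 4 were not called (1 and 6 adjusted over the list alone). Their median was -0.53 in log2 (camera adjusted p = 0.0275, adjusted p = 0.242 with an estimated correlation), including *ptr-10* and *daf-6* (at least 4.26-fold and 5.98-fold lower). That call ended without L4 replicate 5 (adjusted p = 0.0516), without dim probe sets (0.318, with a median of -0.02) and with the 2 groups alone in the fit (0.0521).

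Of the sperm genes, 15 of 72 rose, 14 fell and 43 were not called (16 and 14 adjusted over the list alone). Their median was 0.07 in log2 (camera adjusted p = 0.434), which turned to -0.08 without shared-probe probe sets. Of the early embryonic zygotic genes, 2 of 22 rose, 0 fell and 20 were not called (2 and 0 adjusted over the list alone). Their median was 0.08 in log2 (camera adjusted p = 0.341), the risen genes being *tbx-9* (at least 2.14-fold) and the intestinal factor *elt-7* (1.65-fold). Of the cell cycle and DNA replication genes, 3 of 32 rose, 3 fell and 26 were not called (3 and 3 adjusted over the list alone). Their median was 0.04 in log2 (camera adjusted p = 0.964), with a mean of -0.01. The median turned to -0.0066 after median-centring and -0.0046 without L4 replicate 5. Of the vulva, uterus and somatic gonad genes, 3 of 24 rose, 2 fell and 19 were not called (3 and 2 adjusted over the list alone). Their median was -0.07 in log2 (camera adjusted p = 0.964), the mean also below 0, while the test ran upward. Of the calls, 50.4% were higher (over the alternatives, 44.9% after median-centring to 59.2% after scaling to the hybridisation controls). Without lethargus replicate 1, L4 replicate 3 and Adult replicate 2 together, 4615 probe sets rose and 4152 fell.

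**Figure D2:**
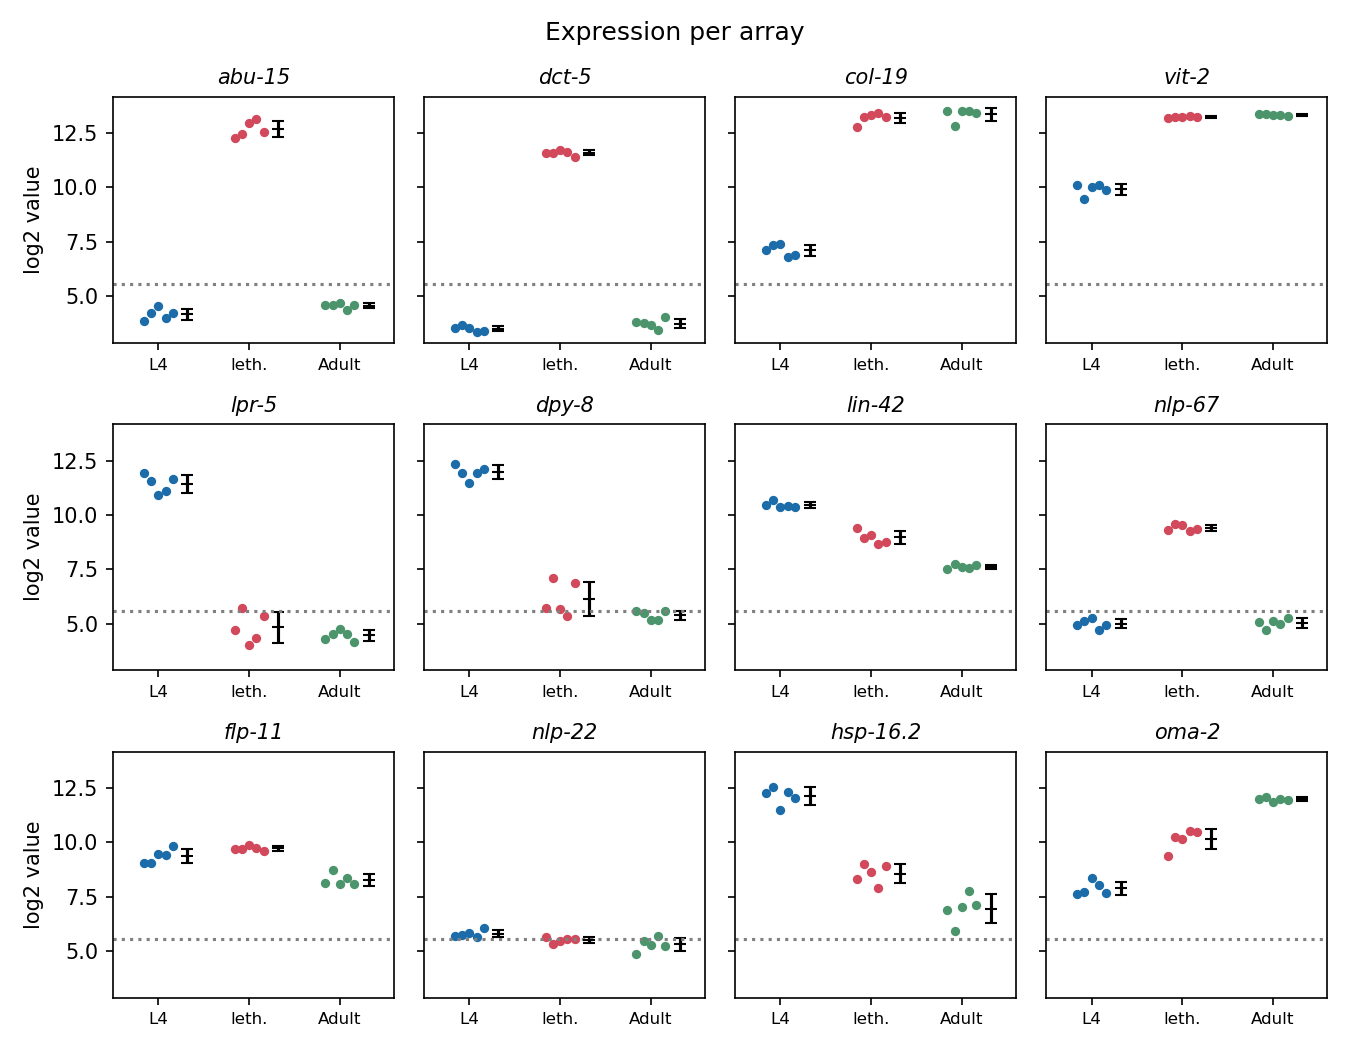
Deposited log2 values of 12 genes on the 15 arrays, 5 per stage, on a common log2 axis. Points are arrays, black bars are the mean ± SD (n = 5) and the dotted line at 5.56 is the background bound; *abu-15* and *dct-5* are above it in lethargus alone, while *nlp-22* lies close to it at every stage.

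The comparison of lethargus with Adult asks which transcripts separate the quiescent animal from the later stage. Many cuticle and neuropeptide genes were higher in lethargus, and most oocyte and cell cycle genes were lower. The *abu-15*, *abu-6* and *abu-8* genes were at least 138-fold, at least 124-fold and at least 137-fold higher, and *dct-5* was at least 65.3-fold higher. The uterine lumen gene *ule-1* was 32.2-fold lower, and 31 of 32 cell cycle genes and 32 of 33 oogenesis genes fell.

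In all, 5715 probe sets (4492 genes) rose and 7147 (5314 genes) fell at an adjusted p of 0.05 or less by limma. The share of calls that were higher was 44.4%, but 25% after median-centring, 23.6% after scaling to the hybridisation controls, 50.2% with cyclic loess and 57.7% at a log2 difference of at least 1. The median over all probe sets was -0.09, and the first 2 of these moved it to -0.34 and -0.37. Among the largest rises, *dbd-20* was 118-fold higher (adjusted p = 1.95e-12) and *tag-297* had 12.01 ± 0.41 in lethargus and 5.15 ± 0.39 in Adult (SD, n = 5 each, adjusted p = 4.65e-13). Among the largest falls, *ule-1* had 6.90 ± 1.04 in lethargus and 11.92 ± 0.16 in Adult (SD, n = 5 each, adjusted p = 5.89e-09). *drd-10* had 4.70 ± 0.22 in lethargus and 9.65 ± 0.54 in Adult (SD, n = 5 each, adjusted p = 2.68e-11). The collagen genes *col-143* and *col-101* were 26.9-fold and 25.1-fold lower, and the Skp1-related genes *skr-7* and *skr-15* were at least 11.1-fold and at least 10.6-fold lower.

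Of the cuticle collagens, 72 of 146 rose, 13 fell and 61 were not called (74 and 13 adjusted over the list alone). Their median was 0.47 in log2 (camera adjusted p = 5.95e-08, adjusted p = 0.166 with an estimated correlation), with *col-91*, *col-120* and *col-60* up 69.7-fold, 63.4-fold and 63.3-fold. Of the adult cuticle collagens, 6 of 8 rose, 0 fell and 2 were not called (7 and 0 adjusted over the list alone). Their median was 3.10 in log2 (camera adjusted p = 0.00153, adjusted p = 0.261 with an estimated correlation), including *col-49* and *col-38* (60.8-fold and 33.4-fold higher). Against L4, 1 of 8 rose in Adult and 7 fell, at a median of -6.09 (camera adjusted p = 0.00147). This call ended with an estimated correlation (0.189) or no shared-probe probe sets (0.0552). No furrow collagen passed. *dpy-8* was at 6.13 ± 0.79 in lethargus (SD, n = 5) and not above background in Adult (adjusted p = 0.0634), and the list had a median of -0.03 with a mean of 0.07, a median that turned above 0 under 5 alternatives, furthest to 0.13 with cyclic loess. *dpy-8* passed without lethargus replicates 1, 3 or 4, taken singly (adjusted p = 0.0467, 0.041 and 0.0137), with array weights (0.0115) and with p-values not doubled (0.0317). Of the molting regulators and enzymes, 20 of 36 rose, 3 fell and 13 were not called (20 and 3 adjusted over the list alone). Their median was 0.92 in log2 (camera adjusted p = 3.48e-04, adjusted p = 0.261 with an estimated correlation), among them the astacin *nas-36* and the Kunitz-domain gene *mlt-11* (at least 13.2-fold and at least 3.81-fold higher). The *mlt-11* call ended without shared-probe probe sets (adjusted p = 0.0517), and of its other probe sets 1 passed, 1 did not and 1 was not above background in either stage. Of the hedgehog-related proteins, 28 of 54 rose, 4 fell and 22 were not called (28 and 4 adjusted over the list alone). Their median was 0.56 in log2 (camera adjusted p = 8.22e-04, adjusted p = 0.138 with an estimated correlation), with *grl-16*, *grl-21* and *grl-27* up 57.8-fold, 53.1-fold and 30.5-fold. Of the apical matrix and zona pellucida proteins, 24 of 50 rose, 4 fell and 22 were not called (24 and 4 adjusted over the list alone). Their median was 0.45 in log2 (camera adjusted p = 8.22e-04, adjusted p = 0.166 with an estimated correlation). Of the patched-related proteins, 14 of 26 rose, 2 fell and 10 were not called (14 and 2 adjusted over the list alone). Their median was 0.76 in log2 (camera adjusted p = 0.00545, adjusted p = 0.203 with an estimated correlation), with *ptr-3* up at least 4.44-fold. Of the astacins, 21 of 36 rose, 6 fell and 9 were not called (21 and 6 adjusted over the list alone). Their median was 0.61 in log2 (camera adjusted p = 5.29e-04, adjusted p = 0.138 with an estimated correlation), with *nas-38*, an astacin linked to lethargus, up at least 20.5-fold. After median-centring and after scaling to the hybridisation controls the medians were smaller but the lists still passed, at 0.21 and 0.19 for the cuticle collagens, 0.30 and 0.28 for the hedgehog-related proteins, 0.20 and 0.17 for the apical matrix, 0.51 and 0.49 for the patched-related proteins and 0.36 and 0.34 for the astacins. Without dim probe sets the medians were 0.82, 1.50, 0.75, 1.30 and 1.54 in the same order. Without shared-probe probe sets the hedgehog-related and astacin medians were 0.36 and 1.11, with the mean of the probe sets the molting median was 0.61, and without the 3 arrays together the patched-related median was 0.44. Without shared-probe probe sets the calls of the adult cuticle collagens and the patched-related proteins ended (adjusted p = 0.0556 and 0.0767).

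Of the FMRFamide-like neuropeptides, 17 of 25 rose, 0 fell and 8 were not called (17 and 0 adjusted over the list alone). Their median was 0.78 in log2 (camera adjusted p = 9.80e-06, adjusted p = 0.138 with an estimated correlation), with *flp-7*, *flp-15* and *flp-4* up 5.38-fold, 4.19-fold and 4.01-fold. Of the other neuropeptide-like proteins, 35 of 52 rose, 2 fell and 15 were not called (35 and 2 adjusted over the list alone). Their median was 0.79 in log2 (camera adjusted p = 2.90e-09, adjusted p = 0.138 with an estimated correlation), with *nlp-67*, *nlp-20* and *nlp-12* up at least 14.4-fold, 7.79-fold and 7.29-fold. Of the sleep and lethargus regulators, 19 of 36 rose, 2 fell and 15 were not called (19 and 2 adjusted over the list alone). Their median was 0.51 in log2 (camera adjusted p = 7.41e-04, adjusted p = 0.138 with an estimated correlation). *flp-11* was 9.73 ± 0.11 in lethargus and 8.27 ± 0.27 in Adult (SD, n = 5 each, adjusted p = 7.00e-07), and *lin-42* was 2.54-fold higher (adjusted p = 1.31e-07), although its second probe set did not pass (-0.15 in log2). *nlp-22* was not above background in either stage. *flp-13* differed by 0.06 (adjusted p = 1.00), a sign that turned after median-centring, quantile normalization again and scaling to the hybridisation controls. Of the synaptic vesicle and transmitter genes, 20 of 37 rose, 4 fell and 13 were not called (21 and 4 adjusted over the list alone). Their median was 0.43 in log2 (camera adjusted p = 0.00258, adjusted p = 0.166 with an estimated correlation). After median-centring and after scaling to the hybridisation controls the medians were smaller but the lists still passed, at 0.53 and 0.51 for the FMRFamide-like, 0.54 and 0.52 for the other neuropeptide-like, 0.26 and 0.24 for the sleep and 0.17 and 0.15 for the synaptic list, the last also at 0.26 with quantile normalization again. Here too, passing is relative to the other genes and does not show that the level itself is higher in lethargus. Without dim probe sets the other neuropeptide-like median was 1.26. In the synaptic list *ida-1*, a dense core vesicle protein gene, was 3.45-fold higher and *tbh-1* and *tdc-1* were 6.00-fold and 2.94-fold lower. Of the epidermal antimicrobial peptides, 12 of 18 rose, 2 fell and 4 were not called (12 and 2 adjusted over the list alone). Their median was 1.37 in log2 (camera adjusted p = 5.29e-04, adjusted p = 0.166 with an estimated correlation), with *cnc-4* up 60.9-fold and *cnc-2* up 11.1-fold, and that call ended without shared-probe probe sets (adjusted p = 0.0617), with a median of 0.79.

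Most oocyte and cell cycle genes fell in lethargus. Of the oogenesis and eggshell genes, 0 of 33 rose, 32 fell and 1 was not called (0 and 32 adjusted over the list alone). Their median was -1.18 in log2 (camera adjusted p = 9.06e-08, adjusted p = 0.303 with an estimated correlation), with the oocyte genes *oma-2* and *nos-2* down 3.54-fold and 3.55-fold. Of the cell cycle and DNA replication genes, 0 of 32 rose, 31 fell and 1 was not called (0 and 31 adjusted over the list alone). Their median was -1.05 in log2 (camera adjusted p = 2.90e-09, adjusted p = 0.181 with an estimated correlation), with the ribonucleotide reductase gene *rnr-2* and the replicative helicase genes *mcm-3* and *mcm-5* down 3.09-fold, 2.76-fold and 2.75-fold. Of the vitellogenins, 0 of 5 rose, 2 fell and 3 were not called (0 and 2 adjusted over the list alone). Their median was -1.03 in log2 (camera adjusted p = 0.161), with *vit-1* down 4.15-fold. The *vit-5* fall (2.14-fold, adjusted p = 0.0228) did not pass without any 1 of 3 arrays (adjusted p = 0.052 to 0.0546). Of the pharyngeal muscle and gland genes, 17 of 26 rose, 1 fell and 8 were not called (17 and 1 adjusted over the list alone). Their median was 1.37 in log2 (camera adjusted p = 1.03e-05, adjusted p = 0.261 with an estimated correlation), and the median was 0.79 without shared-probe probe sets. All 11 *abu* genes, which the list includes, were among the rises. Of the sperm genes, 19 of 72 rose, 5 fell and 48 were not called (13 and 5 adjusted over the list alone). Their median was 0.06 in log2 (camera adjusted p = 0.161), a median that turned to -0.19 after median-centring and -0.21 after scaling to the hybridisation controls. Without shared-probe probe sets the sperm list passed (adjusted p = 0.0499), and with the 2 groups alone the vitellogenins did (0.0328).

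Several lists turned direction with the scaling. Of the body wall muscle structural genes, 10 of 27 rose, 0 fell and 17 were not called (9 and 0 adjusted over the list alone). Their median was 0.20 in log2 (camera adjusted p = 0.0133, adjusted p = 0.261 with an estimated correlation). That median turned to -0.05 after median-centring and -0.08 after scaling to the hybridisation controls. Of the unfolded protein response genes, 11 of 23 rose, 1 fell and 11 were not called (11 and 1 adjusted over the list alone). Their median was 0.19 in log2 (camera adjusted p = 0.00821, adjusted p = 0.261 with an estimated correlation), which turned to -0.07 and -0.09 in the same way. Both calls ended under those scalings (adjusted p = 0.0991 to 0.213) and without shared-probe probe sets (0.113 and 0.0674, with an unfolded protein response median of 0.32). Of the cytosolic ribosomal proteins, 1 of 74 rose, 2 fell and 71 were not called (1 and 1 adjusted over the list alone). Their median was 0.01 in log2 (camera adjusted p = 0.670), with a mean of -0.0023. The median turned to -0.24 and -0.27, which passed as lower (adjusted p = 0.022 and 0.0355), and to -0.03 and -0.01 with quantile normalization again and cyclic loess. Of the vulva, uterus and somatic gonad genes, 10 of 24 rose, 3 fell and 11 were not called (11 and 3 adjusted over the list alone). Their median was 0.11 in log2 (camera adjusted p = 0.0440, adjusted p = 0.270 with an estimated correlation), which turned to -0.14 and -0.16 while the test still passed upward. The last call ended without lethargus replicate 4 or Adult replicate 2 (adjusted p = 0.0516 and 0.0837), with quantile normalization again, cyclic loess, the 2 groups alone, array weights or no shared-probe probe sets, under both other rules for genes with several probe sets, and without the 3 arrays together (0.0514 to 0.133). In these settings its median was 0.05 to 0.19, and without dim probe sets, where it passed, 0.64.

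Of the fasting response genes, 8 of 21 rose, 2 fell and 11 were not called (8 and 2 adjusted over the list alone). Their median was 0.17 in log2 (camera adjusted p = 0.0574), which turned to -0.08 after median-centring and -0.11 after scaling to the hybridisation controls. The list passed without Adult replicates 1 or 2, taken singly (adjusted p = 0.0482 and 0.0395), and with quantile normalization again, a trended robust prior or array weights (0.0398 to 0.0452). The glyoxylate cycle gene *icl-1* was 7.08-fold higher. Of the C-type lectins, 42 of 220 rose, 37 fell and 141 were not called (41 and 35 adjusted over the list alone). Their median was -0.11 in log2 (camera adjusted p = 0.926), with a mean of 0.01 and a median of 0.52 when dim probe sets were left out, which passed as higher (adjusted p = 0.0122). Of the oxidative phosphorylation genes, 4 of 40 rose, 6 fell and 30 were not called (3 and 5 adjusted over the list alone). Their median was 0.04 in log2 (camera adjusted p = 0.551), with a mean of -0.0019. The median turned to -0.21 after median-centring and -0.24 after scaling to the hybridisation controls. Without the 3 arrays together, 6049 probe sets rose and 7153 fell.

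The comparison of Adult with L4 asks how the stages before and after lethargus differ. Most yolk, oocyte and cell cycle genes were higher in Adult, and most molting, furrow collagen and neuropeptide genes were lower. All 5 vitellogenins rose, with a median log2 difference of 3.43 (camera adjusted p = 1.11e-04, adjusted p = 0.158 with an estimated correlation, 5 and 0 adjusted over the list alone), and *vit-5* was 84.9-fold higher. The uterine lumen genes *ule-5* and *ule-1* were at least 136-fold and at least 81.7-fold higher, and 31 of 36 molting genes fell.

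In Adult 7082 probe sets (5274 genes) were higher and 6308 (4912 genes) lower at an adjusted p of 0.05 or less by limma, so 52.9% of calls were higher, but 69.7% after median-centring, 76.7% after scaling to the hybridisation controls, 49.4% with cyclic loess and 46.7% at a log2 difference of at least 1. The median over all probe sets was 0.08, against 0.29 and 0.43 after the first 2 of these. *ule-5* and *stha-3* (at least 158-fold higher) were among the largest rises (adjusted p = 6.34e-13 and adjusted p = 3.17e-13), and the collagen genes *col-129* and *col-8* were 90.2-fold and 88.9-fold higher. *mlt-11*, *lpr-4* and *spia-1* were at least 66.6-fold, at least 91.6-fold and at least 147-fold lower (adjusted p = 1.25e-11, adjusted p = 1.00e-10 and adjusted p = 7.00e-11), followed by *wrt-6*, *lpr-3* and the saposin-like gene *spp-13* (at least 63.6-fold, at least 109-fold and at least 89.8-fold). Of the other probe sets of *mlt-11*, 2 passed and 1 was not above background in either stage, and that of *stha-3* passed.

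Of the oogenesis and eggshell genes, 32 of 33 rose, 0 fell and 1 was not called (32 and 0 adjusted over the list alone). Their median was 2.70 in log2 (camera adjusted p = 1.01e-13, adjusted p = 0.158 with an estimated correlation), and *nos-2* and the Pumilio gene *puf-5* were 25.3-fold and 21.5-fold higher in Adult, and *perm-2* rose by 4.59 on the log2 scale. Of the cell cycle and DNA replication genes, 30 of 32 rose, 0 fell and 2 were not called (30 and 0 adjusted over the list alone). Their median was 1.01 in log2 (camera adjusted p = 2.25e-08, adjusted p = 0.158 with an estimated correlation), with the cyclin genes *cyb-3* and *cye-1* up 3.36-fold and 3.19-fold, and a second probe set of *cyb-3* up by 2.90 in log2. Of the molting regulators and enzymes, 0 of 36 rose, 31 fell and 5 were not called (0 and 31 adjusted over the list alone). Their median was -1.98 in log2 (camera adjusted p = 4.41e-10, adjusted p = 0.158 with an estimated correlation). Of the furrow collagens, 0 of 5 rose, 5 fell and 0 were not called (0 and 5 adjusted over the list alone). Their median was -4.54 in log2 (camera adjusted p = 9.34e-05, adjusted p = 0.158 with an estimated correlation), and *dpy-8* went from 11.96 ± 0.32 in L4 to 5.39 ± 0.21 in Adult (SD, n = 5 each, adjusted p = 1.75e-11). Of the cuticle collagens, 41 of 146 rose, 60 fell and 45 were not called (43 and 60 adjusted over the list alone). Their median was -0.04 in log2 (camera adjusted p = 0.0859), and *sqt-1* fell 116-fold. That median turned to 0.17 after median-centring, 0.06 after quantile normalization again and 0.31 after scaling to the hybridisation controls, and above 0 under 4 other alternatives. The list test, which is relative to the other genes, passed downward after median-centring and that scaling (adjusted p = 0.0132 and 0.00592) and with the 2 groups alone in the fit (0.0335). *hsp-16.2* and *hsp-16.41* were 36.3-fold and at least 33.1-fold lower in Adult than in L4.

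Most measured genes of the neuronal lists were lower in Adult. Of the FMRFamide-like neuropeptides, 2 of 25 rose, 14 fell and 9 were not called (2 and 14 adjusted over the list alone). Their median was -0.45 in log2 (camera adjusted p = 0.00240, adjusted p = 0.158 with an estimated correlation). Of the other neuropeptide-like proteins, 3 of 52 rose, 30 fell and 19 were not called (3 and 30 adjusted over the list alone). Their median was -0.55 in log2 (camera adjusted p = 8.52e-06, adjusted p = 0.158 with an estimated correlation). *flp-7*, *nlp-20* and *nlp-17* fell 4.60-fold, 6.66-fold and 6.12-fold. Of the synaptic vesicle and transmitter genes, 7 of 37 rose, 19 fell and 11 were not called (7 and 19 adjusted over the list alone). Their median was -0.41 in log2 (camera adjusted p = 0.0133, adjusted p = 0.158 with an estimated correlation). Of the body wall muscle structural genes, 0 of 27 rose, 19 fell and 8 were not called (0 and 19 adjusted over the list alone). Their median was -0.37 in log2 (camera adjusted p = 2.23e-04, adjusted p = 0.158 with an estimated correlation), with the troponin gene *tni-1* down 2.42-fold. Of the intestinal digestive proteases, 1 of 17 rose, 12 fell and 4 were not called (2 and 13 adjusted over the list alone). Their median was -0.38 in log2 (camera adjusted p = 0.00383, adjusted p = 0.158 with an estimated correlation), although the trypsin-like gene *try-1* of that list rose by 4.46 on the log2 scale. The protease call ended without shared-probe probe sets (adjusted p = 0.230). After median-centring and after scaling to the hybridisation controls the medians were nearer 0 but the lists still passed, at -0.24 and -0.11 for the FMRFamide-like, -0.34 and -0.21 for the other neuropeptide-like, -0.20 and -0.06 for the synaptic, -0.16 and -0.02 for the muscle and -0.17 and -0.04 for the protease list. Quantile normalization again gave the synaptic list -0.22. Without dim probe sets the other neuropeptide-like and synaptic medians were -0.88 and -0.73, and without shared-probe probe sets the synaptic and muscle medians were -0.62 and -0.57. With the probe set of largest spread the synaptic median was -0.62. *lin-42* fell 7.09-fold, although its second probe set did not pass (-0.23 in log2), *flp-11* fell 2.15-fold, and *nlp-22* fell at least 1.18-fold (adjusted p = 0.00631). The *nlp-22* call ended after median-centring (adjusted p = 0.122) and scaling to the hybridisation controls (0.712). *flp-13* did not pass (0.37, adjusted p = 0.0739) but did without L4 replicate 1 or Adult replicate 5, taken singly (0.0308 and 0.0345), and with median-centring, quantile normalization again, cyclic loess, scaling to the hybridisation controls or p-values not doubled (0.00177 to 0.0387). Of the cytosolic ribosomal proteins, 0 of 74 rose, 11 fell and 63 were not called (0 and 1 adjusted over the list alone). Their median was -0.12 in log2 (camera adjusted p = 0.00340, adjusted p = 0.371 with an estimated correlation), a direction that turned to 0.09 after median-centring and 0.23 after scaling to the hybridisation controls. The ribosomal call ended with both, with quantile normalization again and with cyclic loess (adjusted p = 0.0537 to 0.963). Median, mean and test differed in sign for 4 lists, none of them called. The astacins had a median of 0.13 and a mean of -0.0032, the pharyngeal genes 0.14 and -0.25, the C-type lectins 0.11 and -0.09 and the sperm genes 0.08 and -0.08. The test ran upward for the first pair and downward for the others. Without dim probe sets the lectin median turned to -0.72 and passed as lower (adjusted p = 0.00418), and the astacin median turned to -0.07. Without shared-probe probe sets the sperm median turned to -0.36.

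**Figure D3:**
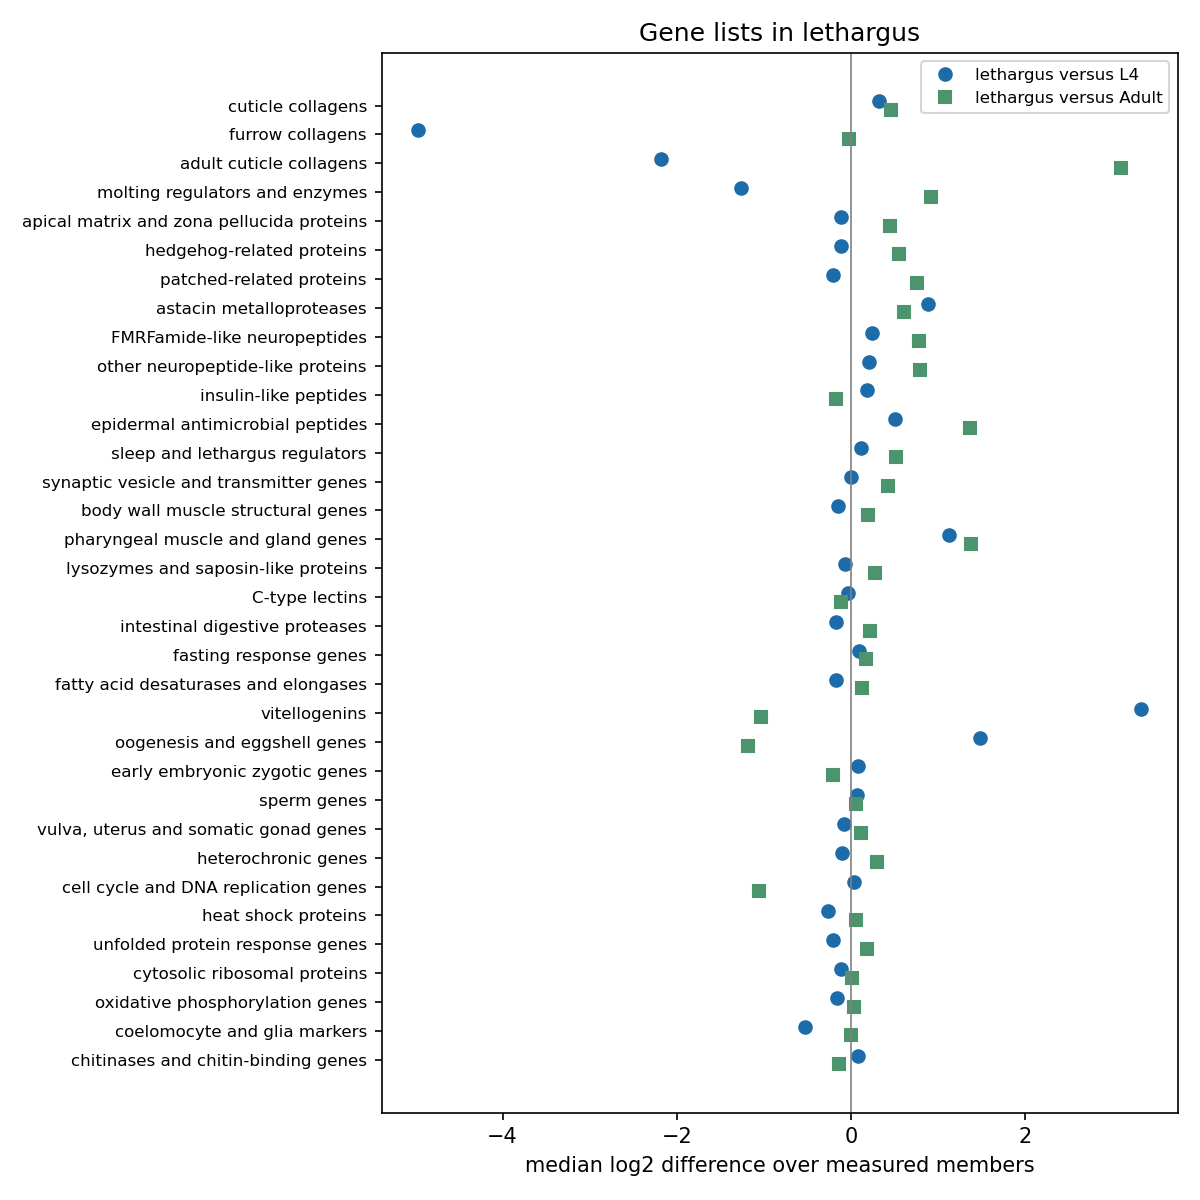
Median log2 difference of the measured members of each of the 34 gene lists in lethargus against L4 (circles) and against Adult (squares). Points are medians over genes with no error bars; furrow collagens lie far below 0 against L4, vitellogenins and oogenesis genes lie above 0 against L4 and below 0 against Adult, and the side changes with the scaling for the squares of the furrow collagen, muscle, protease, fasting, desaturase, sperm, vulva, heat shock, unfolded protein response, ribosomal, oxidative phosphorylation and coelomocyte lists and for the circles of the synaptic, lysozyme, C-type lectin and cell cycle lists.

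A further comparison asks which genes had lethargus above or below both other stages. Genes of the pharyngeal list (mostly *abu* genes), astacins and cuticle collagens were often above both. *abu-10* was 71.1-fold above L4 and 64.7-fold above Adult, and *lam-3*, a laminin gene, was at least 1.96-fold below L4 and at least 2.21-fold below Adult. The second probe set of *abu-10* passed with smaller log2 differences, 2.80 and 2.53, and that of *lam-3* was not above background at any stage. At 1376 genes (1745 probe sets) lethargus was higher than both L4 and Adult, and at 763 genes (998 probe sets) lower than both. The 8 highest were *abu-15*, *dct-5*, *abu-6*, *abu-8*, *dbd-20*, *abu-10*, *col-91* and *idpp-12*, and the 8 lowest were *pugs-8*, *lam-3*, *nhr-235*, *scl-5*, *grd-10*, *acsd-1*, *col-103* and *grd-3*. The count of probe sets below both was 1757 after median-centring and 632 without shared-probe probe sets.

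Of the 2733 genes higher in lethargus than L4, 1376 were also higher than in Adult, 819 rose further in Adult and 538 did not pass against Adult. Of the 2673 genes lower than L4, 763 were also lower than Adult, 891 fell further in Adult and 1019 did not pass against it. Median-centring gave 1331 in place of 763, scaling to the hybridisation controls 471 in place of 891, no dim probe sets 640 in place of 1019, and array weights, the 3 arrays left out together and no shared-probe probe sets 1259, 1341 and 517 in place of 819. Both comparisons use the same 5 lethargus arrays, so part of the overlap may come from them. In 20 simulations with unchanged groups at most 0 probe sets were shared, a value that does not measure this part, since almost none pass there. Independent lists of the same sizes would share 889.9 higher and 1095.1 lower probe sets. With different lethargus arrays in the 2 comparisons (20 splits), the shared counts were 1329.5 higher and 582.5 lower at the median, against 576.8 and 643.9 for independent lists.

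Fisher's exact test over the 17118 genes, with Benjamini-Hochberg adjustment, found more genes higher than both stages than expected among pharyngeal muscle and gland genes (15 of 26, adjusted p = 3.95e-09), astacins (17 of 36, adjusted p = 9.89e-09) and cuticle collagens (41 of 146, adjusted p = 3.93e-11). The same held for hedgehog-related proteins (14 of 54, adjusted p = 0.00114) and epidermal antimicrobial peptides (7 of 18, adjusted p = 0.00349). Fewer than expected were found among C-type lectins (4 of 220, adjusted p = 0.00188), sperm genes (0 of 72, adjusted p = 0.0346) and ribosomal proteins (0 of 74, adjusted p = 0.0346). Excluding dim probe sets ended the hedgehog-related call (adjusted p = 0.0622) and the lectin call (0.882), median-centring also the lectin call (0.0605), and excluding shared-probe probe sets the antimicrobial call (0.221). Median-centring, quantile normalization again, scaling to the hybridisation controls, array weights, permutation p-values and no shared-probe probe sets each ended the sperm and ribosomal calls (adjusted p = 0.0546 to 0.692). At a log2 difference of at least 1 the lectin, sperm and ribosomal calls ended (adjusted p = 0.451, 0.701 and 0.701). Cyclic loess, a trended robust prior and leaving out the 3 arrays together ended the sperm call (0.407, 0.0555 and 0.714). The sperm result ended without any 1 of 10 arrays (adjusted p = 0.0526 to 0.273). The ribosomal result ended without any 1 of 7 (0.0526 to 0.0595). Fisher's test, here and for gene-name classes, takes genes as independent, but some share probes or may vary together. Its p-values do not measure the spread between arrays.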

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

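All tests of explanations in this part, their limits and the 3 patterns weighed were chosen after the results were seen, and the tests of admixture, dilution, normalization and heat stress were revised after a first version of each had given its value, which changed their outcome to open.

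A value is listed here when its gap to the nearest array of its stage exceeded 0.71 of the range of the 5 arrays. This happened in 37 of 402 sets of a gene and a stage, and chance gives about 1 in 20. Adult replicate 2 stood apart in log2 value for *col-101* (11.91), *col-19* (12.82), *dpy-9* (7.86), *flp-15* (10.21), *flp-4* (8.48), *lin-3* (7.93), *nlp-12* (9.82), *npp-22* (10.95), *perm-2* (12.74), *ptr-10* (3.78), *skr-15* (9.55), *try-1* (9.81) and *vit-1* (12.33). Lethargus replicate 1 did so for *col-19* (12.77), *col-39* (12.72), *grl-21* (9.87), *hsp-43* (9.40), *lin-3* (7.12), *mcm-3* (10.20), *nos-2* (9.11) and *vit-5* (12.30). Adult replicate 5 did so for *col-60* (7.72), *dbd-20* (6.34) and *grl-21* (8.10). L4 replicate 3 did so for *col-91* (8.14), *grl-27* (7.43) and *spp-13* (11.54). Adult replicate 1 did so for *col-38* (7.53) and *cyp-32A1* (6.64). Lethargus replicate 4 did so for *grl-16* (12.13) and *tag-297* (11.28). Adult replicate 3 did so for *mcm-5* (11.06) and *qua-1* (4.49). Lethargus replicates 3 and 5 did so for *flp-17* (7.80) and *nlp-17* (11.04). L4 replicate 2 and Adult replicate 4 did so for *lin-42* (10.67) and *ule-1* (12.19). Of 21 sets of an array measure and a stage, 2 stood apart. Adult replicate 2 had a mean correlation with its stage of 0.9866, against 0.9941 to 0.9945 for the other Adult arrays. L4 replicate 5 had a ubiquitin 3' minus 5' difference of 4.81, against 4.55 to 4.60 for the other L4 arrays.

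Lethargus replicate 1 lay nearer to the L4 arrays than the other lethargus arrays did. Mixing of L4 animals or RNA into its pool would give 1 share of L4 RNA for all genes. For 79 genes far higher in L4, the share per gene had a median of 3.04%. It ran from -0.58% at the 10th percentile to 16.8% at the 90th, and 24 genes lay under 0. These genes thus pointed to no common share, though many were close to background in lethargus. At the best single share of 0.5%, 6 genes lay outside the range allowed, and 7 with no L4 RNA at all. The test therefore cannot separate so small a share from none. An array-wide difference such as RNA quality stays open too: across genes its deviation from replicates 2 and 3 correlated at r = 0.492 with the difference of L4 from replicates 4 and 5, against -0.296 to 0.285 for the other replicates. That value lay between 0.3, under which an array-wide difference was to be kept, and 0.6, over which it was to be rejected, and genes are not independent replicates. The design names no group for this pattern, so no biological explanation was tested.

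Neuropeptide, synaptic, muscle and intestinal protease lists were all lower in Adult than in L4. Dilution of somatic RNA by a larger germ line in Adult might lower all of them alike, but the neuropeptide lists shifted by -0.68 ± 0.07 and the muscle list by -0.45 ± 0.07 (log2, SD, n = 5). Their difference of -0.23 was under 2 SD (SD 0.129) while the exact permutation test gave a two-sided p of 0.0476, so dilution stays open. The authors' normalization could also have moved the Adult arrays: after scaling to the hybridisation controls, 0 of 5 lists were lower at an exact permutation p of 0.05 or less, with p of 0.0556 to 0.968. The array differences tested were -0.26 to -0.04 for 4 lists and 0.0028 for the muscle list, and the medians over genes -0.21 to -0.02, which leaves it open. The control signal was 11.70 ± 0.13 in L4, 11.63 ± 0.05 in lethargus and 11.35 ± 0.08 in Adult (log2, SD, n = 5 each), and a difference between the stages themselves was not tested.

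The small heat shock genes *hsp-16.2* and *hsp-16.41* were higher in L4 than in lethargus and Adult. Acute heat or handling stress of the L4 pools may raise them, and then other heat-induced genes should be higher in L4 as well. The 4 such genes measured outside the hsp-16 family were lower in lethargus than in L4, at a median of -0.3725 in log2, and only *dnj-13* passed (adjusted p = 0.0482), a call that ended when any 1 of 12 arrays was left out (0.0531 to 0.126), while *hsp-110* passed without L4 replicate 3 (0.0362). In Adult *hsp-70* was 3.31-fold lower than in L4 (adjusted p = 0.00396), and *hsp-110*, *hsp-1* and *dnj-13* differed by -0.11, -0.005 and -0.14 without passing, signs that turned after median-centring and after scaling to the hybridisation controls. These are fewer genes than the 5 the test needed, so heat or handling stays open, and a biological difference between the stages was not tested.

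Chance assignment of arrays to stages was examined by random splits. For each comparison of 2 stages, 1 of 100 splits of the 10 arrays, the real one, gave as many called probe sets. The real counts were 6966, 12862 and 13390 for lethargus against L4, lethargus against Adult and Adult against L4. The other splits gave at most 1832, 1481 and 1618. For lethargus apart from both stages, 1 of 100 splits of the 15 arrays gave as many, with 2743 against 75 at most in the others. Chance is unlikely for all 4, but no value under 1 in 100 was possible.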

How the results depend on the processing

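Scaling to the hybridisation controls and leaving out 3 arrays together were chosen after seeing the data. Of the results named, 29 of 228 genes, 71 of 102 lists and 12 of 18 classes came to pass or no longer passed under at least 1 alternative, counting a log2 difference of at least 1 and, for lists, an estimated correlation. A sign that turned without a call is not counted there, and the causes were not tested. Median-centring gave 12286 probe sets lower than Adult, 11189 higher in Adult than L4 and 1757 lower than both stages, and a ribosomal median against Adult of -0.24. *hsp-1* passed as higher in Adult than L4 with it (0.20) and with scaling to the hybridisation controls (0.34). The latter gave 3795 higher and 12301 lower than Adult, 13072 higher and 3982 lower in Adult than L4, and ribosomal medians of -0.27 against Adult and 0.23 for Adult against L4. A log2 difference of at least 1, which by construction keeps fewer probe sets, left 1290 higher and 1048 lower than L4, 2495 and 1829 against Adult, 2516 and 2875 for Adult against L4, and 658 and 123 apart from both. It left 8 nuclear hormone receptor (*nhr*) genes against L4 and 4 apart, 1 nucleoporin (*npp*) gene against Adult and 0 proteasome (*rpn*) genes apart. Leaving out shared-probe probe sets, which removes probe sets, gave 2255 higher than L4, 4561 lower than Adult, 4543 higher in Adult than L4 and 632 lower than both. With different lethargus arrays for the 2 comparisons, 582.5 were lower than both. Without dim probe sets the C-type lectin median against Adult was 0.52.

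Same-numbered arrays of different stages share only the number. In 15 same-number pairs the deviations correlated at -0.24 to 0.132, 2 above 0.1, and 4 of 15 arrays correlated best with their own number. With the replicate number as a block, 3291 and 3147 probe sets were higher and lower than L4, 5553 and 6916 than Adult, and 6830 and 6111 in Adult than L4. Of named calls, the block changed only *dpy-8* (adjusted p = 0.0313) and the vulva list (0.0503) against Adult and *dnj-13* against L4 (0.0941). Permutation p-values gave 3081 and 2947, 5275 and 6488, and 6465 and 5935. Without 1 array, the counts ranged from 3111 to 3916 and 2969 to 4046 against L4, 5360 to 5984 and 6639 to 7334 against Adult, 6465 to 7249 and 5998 to 6526 for Adult against L4, and 1576 to 1916 and 798 to 1266 apart from both. Signal over background limits the precision of genes under 5.56 log2, and folds against them are bounds.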

Other observations

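Enriched classes of gene names, tested by Fisher's exact test, are reported here for a selection made after their values were seen. Against L4, 72 of 254 nuclear hormone receptor (*nhr*) genes rose (adjusted p = 6.64e-06), with *nhr-84* 2.96-fold and *nhr-256* 2.35-fold higher. Of the *idpp* genes, 11 of 16 rose (adjusted p = 6.06e-05), led by *idpp-12* (at least 46.6-fold). Of the UDP-glucuronosyltransferase (*ugt*) genes, which conjugate small molecules, 21 of 64 rose (adjusted p = 0.00824), with *ugt-43* up at least 10.9-fold. Of the cytochrome P450 (*cyp*) genes, 22 of 73 rose (adjusted p = 0.0158), with *cyp-32A1* up at least 11.2-fold (7.20 in lethargus for its second probe set, with L4 not above background). Histone (*his*) genes fell in 16 of 26 cases (adjusted p = 3.04e-06), and *bus* genes, many of them acting on surface glycans, in 11 of 14 (adjusted p = 6.64e-06), with *bus-1* down 14.4-fold.

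Against Adult, touch receptor (*mec*) genes rose in 12 of 16 cases (adjusted p = 0.000332), with *mec-17* and *mec-12* up 4.54-fold and 3.60-fold, and *dbd* genes in 10 of 13 (adjusted p = 0.000855). Nucleoporin (*npp*) genes fell in 24 of 26 cases (adjusted p = 6.44e-09), TBP-associated factor (*taf*) genes in 13 of 15 (adjusted p = 2.00e-04) and *bath* genes in 30 of 38 (adjusted p = 7.90e-08), with *npp-22* and *bath-41* down 2.18-fold and 2.87-fold. Apart from both stages, 52 *nhr* genes (adjusted p = 1.10e-08), 10 *idpp* genes (adjusted p = 2.70e-06), 15 *ugt* genes (adjusted p = 0.00383), 15 *cyp* genes (adjusted p = 0.00997) and 9 of 32 *cest* genes (adjusted p = 0.0122) were higher, and 7 *his* genes (adjusted p = 0.00491) and 5 of 13 *rpn* genes (adjusted p = 0.00574) were lower. The *cyp* call against L4 ended without any 1 of 4 arrays (adjusted p = 0.0628 to 0.117). The call apart from both stages also ended without any 1 of 4 (0.0506 to 0.0973). Apart from both stages, the *his* call ended without lethargus replicate 3 (adjusted p = 0.0519) and the *rpn* call without lethargus replicate 2 (0.173). Median-centring and scaling to the hybridisation controls ended the *taf* call (adjusted p = 0.0522 and 0.052), and quantile normalization again, cyclic loess and scaling to the hybridisation controls the *rpn* call (0.0504, 0.121 and 1). At a log2 difference of at least 1, which by construction leaves fewer genes, the *nhr*, *cyp* and *his* calls against L4 ended (8, 8 and 5 genes, adjusted p = 0.728, 0.414 and 0.0565), as did the *npp* and *taf* calls against Adult (1 and 4 genes, 0.933 and 0.136) and, apart from both stages, the *nhr*, *ugt*, *cyp*, *cest*, *his* and *rpn* calls (4, 7, 6, 1, 1 and 0 genes, 0.0647 to 1). With the 2 groups alone or permutation p-values the *cyp* calls ended against L4 (adjusted p = 0.104 and 0.0642) and apart (0.163 and 0.0844). The *cyp* call against L4 also ended with p-values not doubled (adjusted p = 0.0529) and array weights (0.0779), and the one apart with scaling to the hybridisation controls (10 genes, 0.260). Without the 3 arrays together the *ugt* and *cyp* calls against L4 ended (0.149 and 0.236). The *cyp* and *cest* calls ended without shared-probe probe sets (adjusted p = 0.0939 against L4 and 0.180 apart for *cyp*, 0.115 for *cest*), and histone probe sets share probes with one another.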
